A study of Oryza sativa with 6 samples.

How the data were processed

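Total RNA from young uppermost internodes of rice was labelled with biotin and hybridised to Affymetrix rice genome arrays, with 3 wild type (Nipponbare) and 3 coi1-13 arrays, per the labels. The labels call them biological replicates and number them 1 to 3 in each genotype. The deposited table held log2 signals of 57381 probe sets, processed with GCOS 1.4 per the submitters' processing notes, and no further step is stated in the sources used here. The scale was judged from the values: taken as powers of 2, the mean signal after trimming 2% at each end was 499.96 on all 6 arrays, the mark of scaling each array to 500. Array medians ran from 5.55 to 5.56 in wild type and from 5.62 to 5.75 in coi1-13. Values of exactly 0 are the floor of the scale, where values have no order. They numbered 1635 to 1873 per wild type array and 853 to 1328 per coi1-13 array. No 2 arrays were identical.

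Probe sets were joined to genes through the platform annotation held at the repository and named through the gene identifiers of a RefSeq gene table (assembly ASM3414082v1), whose coordinates were not used for any value, only its gene names and gene order. Of 57258 probe sets other than the 123 controls, 22436 had exactly 1 gene, 95 had several and were left unnamed, and 34727 had none in that annotation. They covered 17905 genes, of which 2457 had a name other than a locus or clone number, so 88.3% of the called probe sets had no named gene. Different probe sets of a gene were kept apart in the counts, and the one with the highest mean signal stood for the gene in list tests. Of 2773 genes with more than 1 tested probe set, 52 had probe sets called in opposite directions, none of them a gene named in the text, where a probe set that did not pass is given beside one that did for C3H2, Rictpi2, Pht1;1 and UAM3.

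The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on the deposited log2 values without rescaling and without a block, over the 34355 probe sets in the upper 60% by mean signal (a mean log2 signal of at least 4.37). Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values in the text are from this test unless a list test is named. Gene lists were tested with camera at a preset correlation of 0.01 over 16706 genes, 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists, and lists with under 5 tested genes were only counted; an estimated correlation and fry stood beside it. By fry, which asks whether the genes of a list move on balance 1 way, the JAZ and heat shock lists had p-values of 3.6e-06 and 5.2e-05. It does not compare a list with the other genes, and lists that did not pass by camera had low fry p-values too. Those of the WRKY factors and aquaporins were 0.00091 and 0.00097. The design, the tests, 18 gene lists and the rule for naming genes were set before the data were examined. The rule took all COI1 family genes, the 12 largest rises and 12 largest falls among called probe sets of a named gene whose groups did not overlap, and up to 4 genes with the smallest p from each list. The other JAZ family members, C6, RTS and PTC1 were named outside it, after their values were seen, and the clock genes outside it for a test written before theirs were. Of the 18 lists, 4 matched no gene and 5 more held under 5 tested genes, since the annotation gave symbols but no descriptions, and 25 symbol lists were then added.

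A group in which none of the 3 arrays exceeded the highest of 33 negative control probe sets on that array was taken as not above the negative controls. Such folds are given as at least N-fold: the mean of the brighter group against the mean of those highest controls over the arrays of the dimmer group. Other folds are powers of 2 of the difference in log2 signal. The highest controls had log2 signals of 4.93 to 5.11 on wild type arrays and 5.26 to 5.56 on coi1-13 arrays. A dim signal was thus counted more readily as not above them in coi1-13.

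Within groups, arrays correlated at Pearson's r of 0.977 to 0.980 across the tested probe sets, and between groups at 0.944 to 0.946, where probe sets are not independent replicates. The first principal component held 58.5% of the variance. The difference between 3' and 5' control probe sets of GAPDH was 1.96 ± 0.14 in wild type and 1.92 ± 0.08 in coi1-13 (SD, n = 3 each), that of actin 3.22 ± 0.07 and 3.16 ± 0.02, that of cyclophilin 0.97 ± 0.15 and 0.75 ± 0.10, and that of ubiquitin -0.51 ± 0.03 and -0.56 ± 0.04. Of 7 rice actin control probe sets, 6 were lower in coi1-13 at an unadjusted p under 0.05, by 0.40 for 1 of the 3' probe sets, but none of the 90 control probe sets outside the negative controls passed after adjustment. The controls were fitted apart from the other probe sets, so this does not show that actin was unchanged.

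The scripts were tested on simulated data with the means and spreads of the 34355 tested probe sets, in 3 arrays against 3. Of 100 probe sets changed 2-fold, 69% were recovered, and of 100 changed 4-fold, 86%, with 15 unchanged probe sets among 170 calls. Only these 200 of the 34355 were changed, whereas 35.9% were called in the data. A call in the simulation therefore needed a smaller unadjusted p, and these rates do not measure recovery in the real comparison. Raising the JAZ list alone led camera to call that list and no other. The simulated genes varied independently of each other, so this does not test false calls of lists whose genes are correlated. Alternatives covered the scaling between arrays, a pseudocount of 32, filters on dim probe sets, the variance model, the replicate number as a block, each array left out in turn and the list test.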

Results

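The data set compared transcript levels in young uppermost internodes of rice (Oryza sativa) between the wild type cultivar Nipponbare and coi1-13, which the labels give as a mutant. COI1 is the F-box protein through which plants perceive jasmonate, a hormone of defence and development, and the comparison asks which transcripts differ between these genotypes in the elongating stem below the panicle. Biotin-labelled cRNA from 3 biological replicates of each genotype was hybridised to 6 Affymetrix rice arrays. The values were log2 signals, already scaled to 1 level on all arrays, and precision was limited by the 3 arrays per group. Between 52.1% and 56.4% of probe sets on an array lay above its highest negative control.

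The 3 COI1 family genes were measured first, since the genotype is named after one of them. COI1A had a log2 signal of 12.65 ± 0.05 (SD, n = 3) in wild type and 12.55 ± 0.05 (SD, n = 3) on the arrays labelled coi1-13, a difference of -0.11 ± 0.04 (SE) that did not pass the test (adjusted p = 0.0582, limma). COI1B stood at 12.58 in both groups (adjusted p = 0.983), and COI2 at 11.21 ± 0.07 and 11.12 ± 0.13 (SD, n = 3 each; adjusted p = 0.343). The labels do not say what the mutation does to the transcript, so these levels do not check which arrays hold mutant RNA, and all directions below rest on the labels. COI1A passed the threshold under some alternatives, and its log2 change under median centring was -0.23 (adjusted p = 0.00234).

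Genes of the JAZ repressors, which COI1 targets for degradation, were mostly higher in coi1-13. The list fixed first held 16 tested genes, 13 JAZ genes and the TIFY relatives GATA17, GATA18 and GATA20. Of these 11 rose, none fell and 5 did not pass, with the same 11 adjusted over the list alone. Of the 13 JAZ genes alone 10 rose and 3 did not pass (camera adjusted p = 3.9e-06; adjusted p = 0.0566 with an estimated correlation). JAZ10 rose 2.97-fold, from 9.67 ± 0.11 to 11.24 ± 0.04 (SD, n = 3 each), JAZ12 rose 2.66-fold, from 11.26 ± 0.03 to 12.67 ± 0.08, and JAZ11 and JAZ6 rose 2.20-fold and 1.99-fold. JAZ5, JAZ13, JAZ4, JAZ8 and JAZ3 rose by 1.25, 0.79, 0.58, 0.50 and 0.45 on the log2 scale. JAZ9 rose by 0.31, a call lost under median centring (0.19, adjusted p = 0.128), as was that of GATA17 (0.22, against 0.10 with adjusted p = 0.315). GATA18 was called lower there (-0.25, adjusted p = 0.0164). JAZ1, JAZ7, GATA18 and GATA20 differed by 0.11, 0.01, -0.13 and 0.13 and did not pass. JAZ2 did not pass either, but it was above the negative controls on only 2 wild type arrays and no coi1-13 array, so its difference was not measured. The list of 16 had a median log2 change of 0.48 and was higher in coi1-13 than other genes by camera (adjusted p = 1.6e-05), but not with the correlation between genes estimated from these arrays (adjusted p = 0.121 with an estimated correlation).

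**Figure D1:**
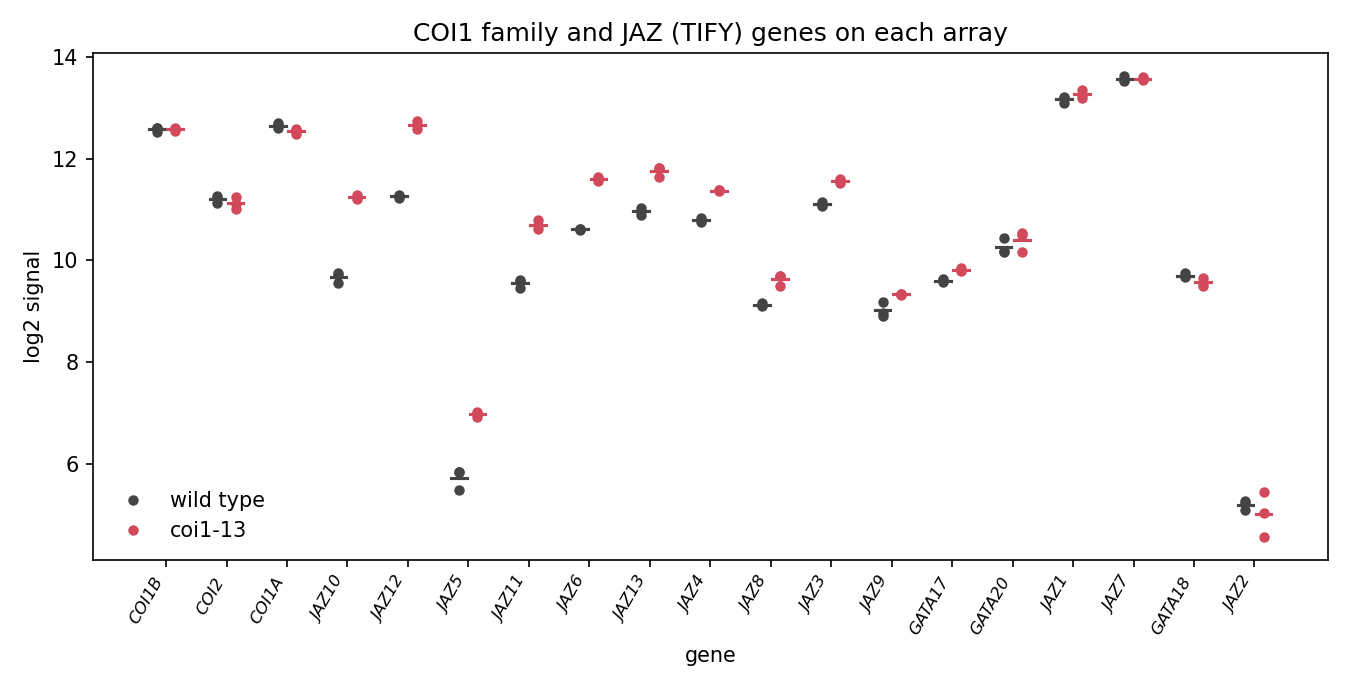
Log2 signal (vertical axis) of the COI1 family genes and the 16 tested genes of the JAZ list (horizontal axis); points are single arrays, 3 per group, and short lines are group means. JAZ10 and JAZ12 were separated by 1.57 and 1.41 between the groups, while COI1B stood at 12.58 in both.

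Across the whole array, the steepest falls among probe sets of named genes were on 2 genes for CCCH zinc finger proteins. C3H40 had a log2 signal of 11.81 ± 0.05 (SD, n = 3) in wild type and was not above the negative controls on any coi1-13 array. Its signal was therefore at least 87.2-fold lower, and a sequence difference under its probes stays open as a cause. The C3H2 probe sets differed: one fell 33.0-fold, from 12.50 ± 0.09 to 7.46 ± 0.42 (SD, n = 3 each), while a brighter one did not pass (12.89 in wild type and 12.80 in coi1-13, adjusted p = 0.135). A fall of the gene is therefore not established. ASMT, a methyltransferase gene of the last step of melatonin synthesis, showed the steepest named rise, 31.3-fold, from 6.20 ± 0.34 to 11.17 ± 0.07 (SD, n = 3 each). CYP714D1 (EUI1), whose product deactivates gibberellin, fell from 8.23 ± 0.08 to 5.43 ± 0.65 and stayed above the negative controls on 1 of the 3 coi1-13 arrays.

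The other large rises included BC1L9, a COBRA-like wall protein gene read by 2 probe sets (8.37-fold and 6.81-fold), BHLH148, a bHLH transcription factor gene (8.04-fold), RAA1 (7.67-fold), the aquaporin gene PIP1-3 (7.59-fold), the calmodulin-like gene CML31 (7.20-fold) and the glutaredoxin gene GRXC15 (4.94-fold). The homeobox gene WOX6 rose too, with 1 of the 3 wild type arrays above the negative controls. A peroxidase gene, the nicotianamine aminotransferase gene NAAT1 and the cytokinin-activating enzyme gene LOGL6 were not above the negative controls in wild type and were at least 2.37-fold, 2.50-fold and 1.71-fold higher in coi1-13. Among the other large falls, an agglutinin gene, the beta-glucosidase gene BGLU38, the cell wall invertase gene CIN3 and OPR12, of the oxophytodienoate reductase family, were not above the negative controls in coi1-13, and were at least 11.9-fold, 3.70-fold, 1.96-fold and 1.65-fold lower. For the agglutinin gene, as for C3H40, a sequence difference under the probes stays open. CYP703A3, a fatty acid hydroxylase gene of the anther, fell 8.22-fold and RH2 6.40-fold. One probe set of Rictpi2 fell 6.86-fold, but a brighter one did not pass (0.09, adjusted p = 0.107). The beta-expansin gene EXPB9 and a probe set of the phosphate transporter gene Pht1;1 fell too, with 2 and 1 of the 3 coi1-13 arrays above the negative controls. A brighter Pht1;1 probe set did not pass. Adjusted p-values of these 24 probe sets ran from 3.4e-10 (C3H40 and CML31) to 0.0263 (Pht1;1). The call of Pht1;1 was lost when any single wild type array was left out, at adjusted p-values from 0.0506 to 0.0737, and that of OPR12 without wild type replicate 1 (adjusted p = 0.0662). Without the variance trend the calls of LOGL6, OPR12 and Pht1;1 were lost (adjusted p = 0.0659, 0.0698 and 0.1275).

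**Figure D2:**
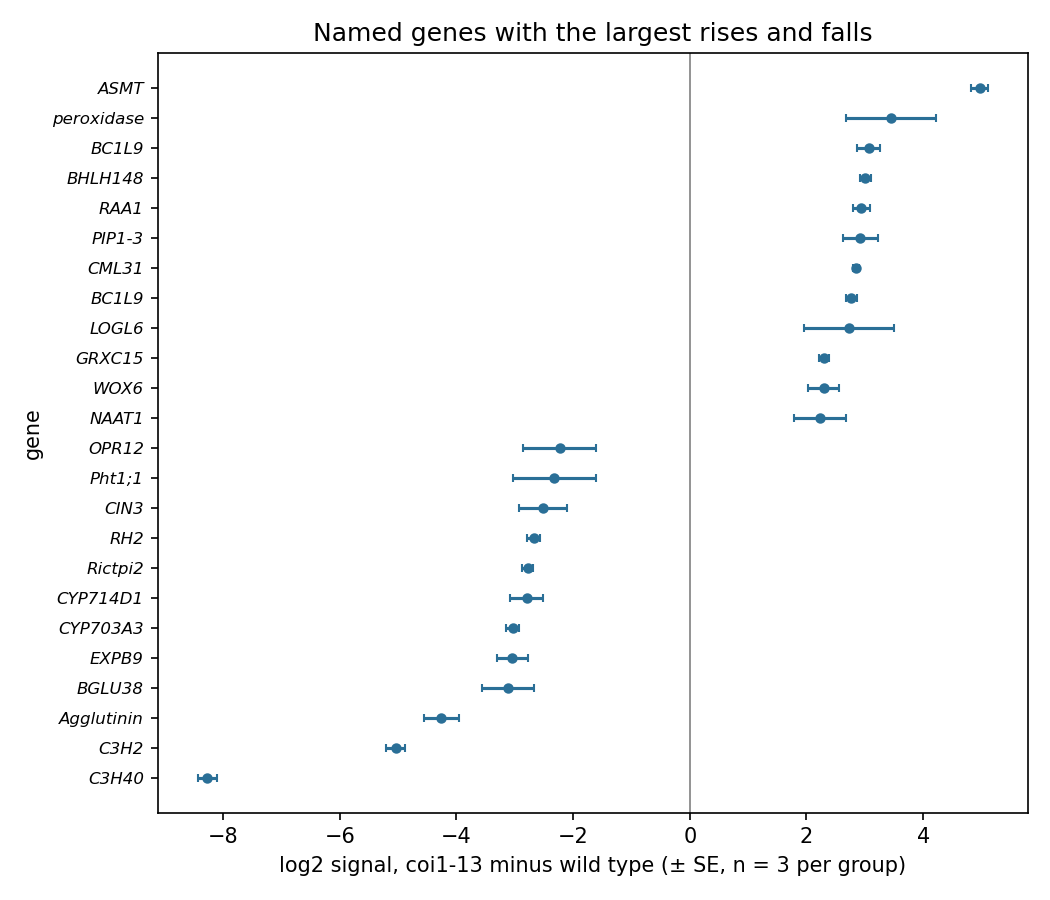
Difference in log2 signal between coi1-13 and wild type (horizontal axis; points are limma estimates and bars ± SE, 3 arrays per group) for the 12 probe sets of named genes with the steepest rises and the 12 with the steepest falls (vertical axis). The signal of C3H40 was at least 87.2-fold lower and ASMT rose by 4.97. Where a group was not above the negative controls the point is not a measured size. BC1L9 appears more than once because 2 probe sets read it.

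In all, 5679 of 34355 tested probe sets were higher and 6668 lower in coi1-13 (limma, adjusted p under 0.05), 35.9% of those tested. Most of these differences were small, since 84.8% of the calls were under 2-fold, and 1188 higher and 686 lower probe sets changed at least 2-fold. The 3 values of 1 group lay wholly above those of the other in 47.5% of tested probe sets, where chance gives 10%. Centring each array on its median moved the median log2 change of all tested probe sets from -0.01 to -0.13 and left 3721 higher and 9522 lower, so the share of calls that were higher went from 46.0% to 28.1%. The array medians were higher in coi1-13 and lay near the highest negative controls, so this centring rests on dim probe sets.

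Of the 18 gene lists fixed before the data were examined, 9 held at least 5 tested genes, and 2 of them passed by camera. Besides the JAZ list, heat shock protein genes were lower: of 23 tested, 15 fell, 4 rose and 4 did not pass (adjusted over the list alone, 16 fell and 4 rose), with an adjusted p = 0.0123, which became an adjusted p = 0.256 with an estimated correlation. The small heat shock protein genes HSP21.9, HSP16.9B, HSP17.7 and HSP23.2 fell by 1.55, 0.78, 0.67 and 0.59 on the log2 scale. A wider list that added heat shock factors did not pass (adjusted p = 0.724), with 14 genes that rose, among them HSFC1B by 0.59, and 16 that fell. The defence protein and ethylene response factor lists, with 3 and 2 of 6 genes each that rose and none that fell, missed the threshold (adjusted p = 0.0721 for each), and chia4a, a chitinase gene, and DREB1G rose 3.72-fold and 3.29-fold. WRKY transcription factor genes went both ways (3 of 6 rose and 2 fell; adjusted p = 0.506): WRKY71 and WRKY51 rose, 3.19-fold and 1.53-fold, while WRKY76 fell 4.45-fold and WRKY62 was at least 2.03-fold lower. The fixed lists of auxin response (7 of 25 rose and 9 fell; median -0.09, mean 0.02), cell division (1 of 6 rose and 2 fell), panicle markers, which matched only MADS-box genes and no anther or pollen gene (6 of 27 rose and 10 fell), and terpenoid phytoalexins (none of 5 passed) did not pass either (adjusted p = 0.736 for each). Adjusted over the list alone, 7 panicle genes rose and 11 fell, and the other counts were the same.

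Because most genes carried no description, 25 lists built from gene symbols were added after the annotation was seen, before any difference between groups was computed. Most fixed lists lie wholly within a symbol list, so the lists are not independent. Of the 23 with at least 5 tested genes, 6 were higher and 5 lower in coi1-13 by camera. Genes for chitinases, germins, protease inhibitors and PR proteins were higher, with 21 of 33 that rose, 3 that fell and 9 that did not pass (adjusted p = 3.9e-06; adjusted p = 0.0566 with an estimated correlation). Among them the chitinase gene Cht4 rose 4.16-fold, the germin gene GER2 2.37-fold and the cystatin genes OC-II and OC-VIII 2.11-fold and 1.60-fold. Cytokinin genes were higher, with 19 of 27 that rose and 2 that fell (adjusted p = 3.9e-05; adjusted p = 0.0566 with an estimated correlation). They included genes of hormone activation, LOG (2.32-fold) and LOGL1 (1.87-fold), of its breakdown, CKX4 (3.42-fold), and the response regulator gene RR21 (1.67-fold).

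Of 24 abscisic acid and dehydration genes, 15 rose, none fell and 9 did not pass (adjusted p = 0.000117; adjusted p = 0.0909 with an estimated correlation). Adjusted over the list alone, 2 fell. ABA8OX1, which encodes an abscisic acid catabolic enzyme, rose 4.06-fold, the kinase genes SAPK2 and SAPK1 1.51-fold and 1.49-fold, and EM, a late embryogenesis gene, 1.33-fold. Genes of sucrose cleavage and sugar transport were higher as a list, with 14 of 36 that rose, 8 that fell and 14 that did not pass (adjusted p = 0.0246; adjusted p = 0.119 with an estimated correlation). The sugar transporter genes SWEET16 and SUT1 rose 2.91-fold and 2.59-fold, the invertase gene CIN1 2.57-fold and the sucrose synthase gene SUS4 1.89-fold. That call was lost with all probe sets of each gene (adjusted p = 0.0765). ERF and DREB genes passed narrowly (3 of 7 rose; adjusted p = 0.0431; adjusted p = 0.182 with an estimated correlation), and lost the call under 6 other alternatives as well.

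Cell wall and cell division genes were lower by the symbol lists, though the cell division list fixed first did not pass. Of 34 genes for expansins and cell wall hydrolases, 20 fell, 5 rose and 9 did not pass (adjusted p = 0.0157; adjusted p = 0.142 with an estimated correlation). The expansin genes EXPA6, EXPB6 and EXPB11 fell 1.91-fold, 1.72-fold and 1.45-fold, while the expansin-like gene EXLA2 rose 1.73-fold. Of 46 cellulose and hemicellulose genes, 26 fell, 5 rose and 15 did not pass (adjusted p = 0.00503; adjusted p = 0.0868 with an estimated correlation). UAM3, XOAT11 and the cellulose synthase gene CESA8 fell by 0.62, 0.51 and 0.46 on the log2 scale (a dimmer UAM3 probe set did not pass), against the rise of BC1L9 in the same list. Of 87 cell division genes, 42 fell, 7 rose and 38 did not pass (adjusted p = 0.000473; adjusted p = 0.0566 with an estimated correlation), among them the cyclin gene CYCB1-1, which fell 1.61-fold, the kinesin genes KIN14N and KIN7K, 1.54-fold and 1.30-fold, and the histone gene H2B.11, 1.21-fold. Ribosomal protein genes fell by small amounts in 17 of 25 cases, with 1 that rose (adjusted p = 0.00411; adjusted p = 0.127 with an estimated correlation), such as RPL7A-2 by 0.29 and RPL3 by 0.25.

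Anther, pollen and meiosis genes, listed as markers of neighbouring panicle tissue, were lower on the same arrays, with 10 of 20 that fell, none that rose and 10 that did not pass (adjusted p = 0.00552; adjusted p = 0.0909 with an estimated correlation). Adjusted over the list alone, 12 fell and 2 rose. Besides CYP703A3, the tapetum genes EAT1, C4 and RAFTIN1 fell 2.28-fold, 1.88-fold and 1.32-fold. The floral MADS-box symbol list held the same 27 genes as the fixed panicle list and likewise did not pass (adjusted p = 0.763), with MADS14 up by 0.40 and MADS1 down, from 12.21 ± 0.06 to 11.82 ± 0.03 (SD, n = 3 each). Photosynthesis genes, listed as markers of leaf tissue, did not pass as a list (7 rose, 3 fell, 12 did not pass; adjusted p = 0.223); LIR1 and PSAH rose by 0.56 and 0.51, and PORA, an enzyme gene of chlorophyll synthesis, fell by 0.78.

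**Figure D3:**
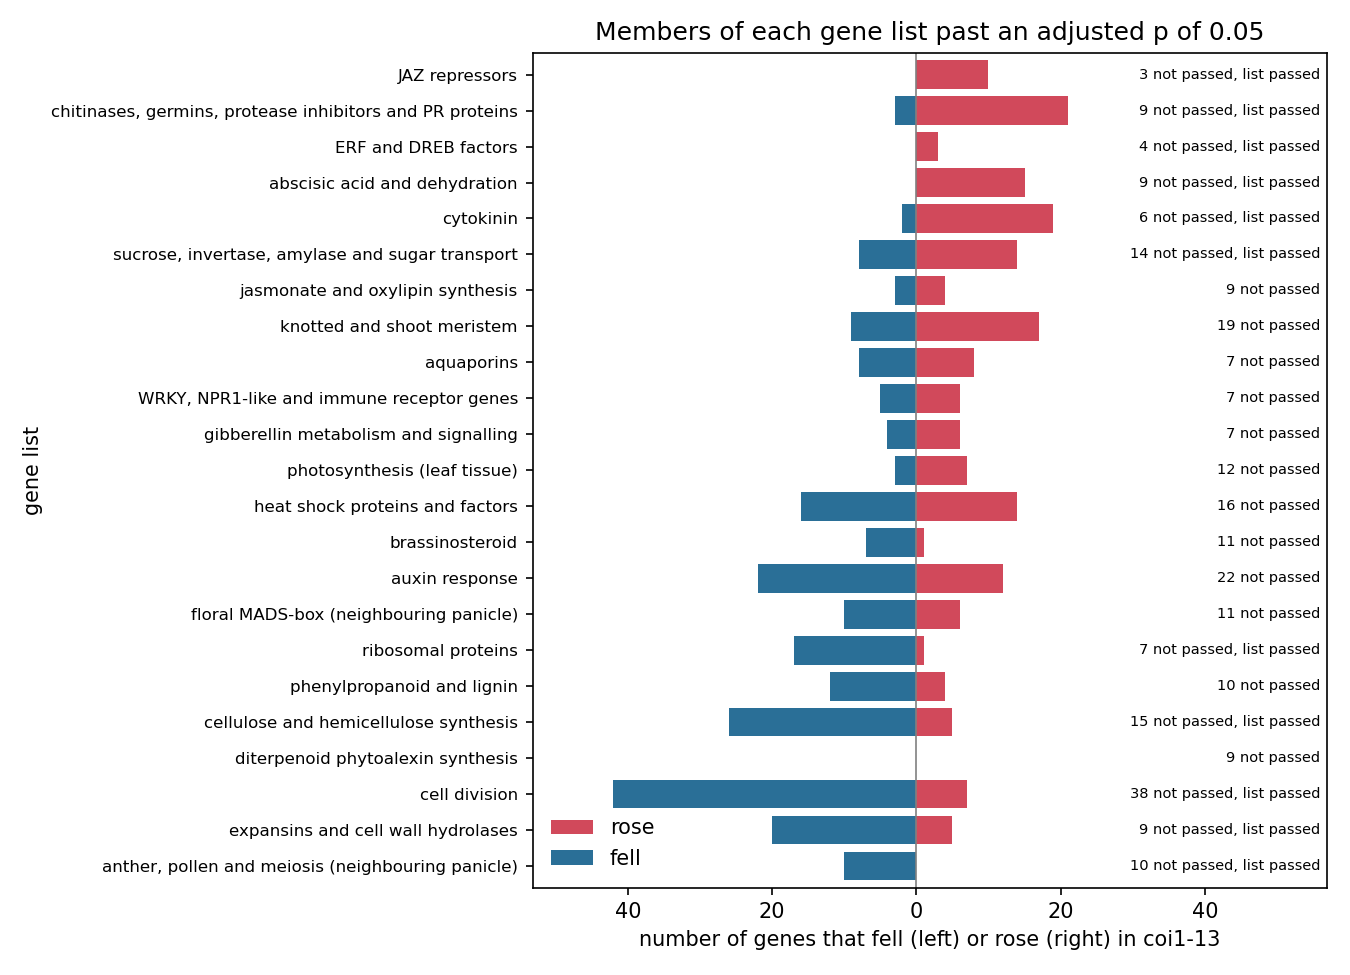
Number of genes that fell (bars to the left) or rose (bars to the right) in coi1-13 past an adjusted p of 0.05 (horizontal axis) in each of the 23 tested symbol lists (vertical axis), ordered by median log2 change, 3 arrays per group; the text at the right gives the genes that did not pass and the lists that passed camera. Cell division had 42 genes that fell and 7 that rose, and cytokinin 19 that rose and 2 that fell.

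Hormone lists other than these did not pass. Of 17 gibberellin genes, 6 rose, 4 fell and 7 did not pass (adjusted p = 0.489), with the CYP714D1 fall beside rises of CIGR1 (1.86-fold) and the biosynthetic gene GA20OX3 (1.30-fold); the list had a median of 0.01 and a mean of -0.09, and camera ranked it upward. Of 16 jasmonate and oxylipin synthesis genes, 4 rose, 3 fell and 9 did not pass (adjusted p = 0.538). OPR1 and OPR13 rose by 0.92 and 0.25, the allene oxide cyclase gene aoc by 0.15, and LOX2 fell by 0.44, with the calls of OPR13 and aoc lost under median centring (adjusted p = 0.0957 and 0.638). Of 56 auxin genes, 12 rose, 22 fell and 22 did not pass (adjusted p = 0.462); IAA6 rose 2.35-fold and GH3.2, which encodes an auxin-conjugating enzyme, fell 2.92-fold. Of 19 brassinosteroid genes, 7 fell, 1 rose and 11 did not pass (adjusted p = 0.0816), with CPD2 1.42-fold lower.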

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

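The lists built from symbols were chosen after the annotation was seen, and the other alternatives before the data were examined. Counts of higher and lower probe sets stayed within 1.5 times the values given, except for 3721 higher under median centring and 1188 higher and 686 lower when a 2-fold change was also required, a criterion that can only remove calls. The counts ran from 4917 to 5275 higher and from 5647 to 6123 lower when 1 array was left out. Of the lists fixed first, 2 were higher under median centring, and between 1 and 2 with 1 array left out; the addition was the ethylene response factors, with an adjusted p = 0.0464 without coi1-13 replicate 3. With an estimated correlation 0 were higher and 0 lower: the JAZ list had an adjusted p = 0.121, with its median of 0.48 not touched. That setting changes the variance in the test and also bases it on the 4 residual degrees of freedom. The cytokinin list lost its call there although its estimated correlation, -0.033, lay below the preset 0.01. A call lost under that setting therefore does not by itself show that the genes of a list are correlated. The symbol lists gave 6 higher and 5 lower, and of these 11 lists 0 passed with an estimated correlation, while 9 passed under all other alternatives. Of the COI1 family genes, 1 (COI1A) passed under quantile normalization, 1 under median centring and 1 in the upper 40% by mean signal; between 0 and 1 passed with 1 array left out, COI1A being called without wild type replicate 2 and without coi1-13 replicate 3; the cause was not tested. Of 132 called probe sets of named genes, 118 kept the call under all alternatives that tested them. EREBP1 was the only one to change sign, at -0.0273 under median centring (adjusted p = 0.711). Arrays of the same number did not deviate together (r of -0.0029, 0.0011 and 4e-04 for replicates 1, 2 and 3, and up to 0.0069 for other pairs), so they shared only a number; with it as a replicate block 5481 probe sets were higher and 6336 lower, and the lists called were the same. Only 52.1% to 56.4% of probe sets on an array lay above its highest negative control, and small differences below it could not be measured.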

Other observations

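Tests of array scaling, of exchanged labels and of the share of anther tissue were chosen after the JAZ and anther results were seen, and the others before theirs.

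Lists that did not pass still held genes that did. Of 23 aquaporin genes, 8 rose, 8 fell and 7 did not pass (adjusted p = 0.315), with NIP2-1, TIP1-2 and TIP3-1 up 3.19-fold, 2.72-fold and 2.03-fold and NIP4-1 down by a log2 change of -0.72. Of 45 homeobox, knotted and shoot meristem genes, 17 rose, 9 fell and 19 did not pass (adjusted p = 0.0684; 0.0219 after median centring, where the list's median was -0.05), and HOX24, Hox22, HOX15 and HOX6, of the HD-Zip family, rose by 1.01, 0.96, 0.76 and 0.64. In the phenylpropanoid and lignin list 12 of 26 genes fell and 4 rose (adjusted p = 0.462), with the laccase gene LAC7 up 1.87-fold and LAC4 down by a log2 change of -1.16. None of 9 diterpenoid phytoalexin genes passed. Of 18 WRKY, NPR1-like and immune receptor genes, 6 rose and 5 fell (adjusted p = 0.538), with a probe set of NPR1 up 1.55-fold (a brighter one rose by 0.18) and the chitin receptor gene LYP4 down by a log2 change of -0.80.

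Transcripts known from the anther were bright in these internode samples of both genotypes. RTS had a log2 signal of 14.40 ± 0.05 in wild type and 14.29 ± 0.08 in coi1-13 (SD, n = 3 each), and C6 13.85 ± 0.01 and 13.74 ± 0.06, above the negative controls on 6 of 6 arrays, while the labels name the internode as the tissue. Panicle tissue harvested with it is a candidate source. If signals follow transcript level in proportion, a smaller share of it in coi1-13 would lower transcripts found only there about equally. Their falls would then be about as large as that of CYP703A3, which fell by 3.04. The 18 other anther, pollen and meiosis genes above the negative controls on all wild type arrays changed by a median of -0.37 (SD over the genes 0.54). They ran from PTC1 (7.22 ± 0.45 to 5.34 ± 0.42, above the negative controls on 2 of the 3 coi1-13 arrays) and EAT1, which fell by 1.19, to genes that did not pass. The changes were thus unequal over the list. CYP703A3 was taken for comparison as the gene of this list that fell most, so the others were bound to fall less. Which of the 18 are read from panicle tissue alone was not tested. The comparison therefore does not decide how far a smaller share caused the CYP703A3 fall. A smaller share as all or part of the cause, a panicle at another stage, or a change within anther cells stays open.

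Of the called probe sets, 125 (99 lost and 26 gained in coi1-13, C3H40 and the agglutinin gene among the losses) were not above the negative controls in 1 group and at least 4-fold brighter than them in the other. The highest controls were brighter on the coi1-13 arrays, so losses and gains were not judged against the same level. Only 51 of the 125 had exactly 1 gene in the annotation, so most could not be placed along the genome. Among the 47 genes with such a probe set placed in gene order, 16 pairs lay within 5 tested genes of each other. This was 25.0 times the mean of 10000 shuffles (permutation p = 0.0001, the smallest they can give), so segments of another rice genotype in coi1-13 are a candidate explanation. The genes formed runs of 5, 3 and 3 close members on chromosomes 11, 2 and 4. A run gives several pairs, so the pairs are not independent and a few places weigh heavily in the ratio. Pairs 6 to 50 tested genes apart were 7.004 times as frequent as in the shuffles (permutation p = 0.0001), which argues against copies side by side or small deletions as the whole cause. Sequence differences under the probes stay open, as does an untested effect of the coi1-13 genotype on neighbouring genes: other probe sets of 13 such genes changed in the median by 0.54 times as much, but the divisor rests on signals not above the negative controls, some pairs enter in both directions, and the shares spread widely. In 1 unnamed gene, singled out after its values were seen, one probe set was at least 181-fold lower in coi1-13 and the other at least 126-fold higher.

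JAZ genes are known as jasmonate-induced, and the direction in an arm named after the jasmonate receptor invites a second look. Scaling between arrays is argued against, since the lowest JAZ list median under quantile normalization or median centring was 0.36. The list also passed under both, but camera compares it with the other genes, so centring could hardly remove that call. Harvest at another time of day stays open: all 7 clock genes had higher signals in coi1-13, by a median of 0.247. This lay just under the 0.25 set beforehand as a sign against such a cause, too narrowly to decide. PRR73, GI and PRR95 rose by 0.75, 0.54 and 0.53, each past the threshold. DTH7 (PRR37), PCL1 and PRR1 passed as well, with rises of 0.25, 0.16 and 0.15. Only the CCA1 gene (LHY) did not pass (0.12, adjusted p = 0.515). The smallest of these rises depend on the scaling, since median centring moved the median change of all tested probe sets from -0.01 to -0.13. Exchanged labels cannot be told apart from a true difference, because COI1A and COI1B differed by only -0.0533 on average. An effect of the genotype itself stays open and was not tested by other means.

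The real grouping was the only 1 of the 10 splits of the 6 arrays into 3 and 3 that called as many probe sets, 12347 against at most 0 in the others. For symbol lists it was also 1 of 10, with 11 lists called against up to 8 in the others. With 10 splits no share under 0.05 can be reached. Each other split also mixes the genotypes, so their difference widens its residual spread and part of it stays in the contrast. The counts of the other splits are therefore no baseline for chance, for probe sets or for lists.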
